A study of Danio rerio with 184 samples.

How the data were processed

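Single sorted hair cells from zebrafish larval trunks were sequenced with mcSCRB-seq, a plate-based method that tags the 3′ end of each transcript with a cell barcode and a UMI, per the labels' protocols. The deposited table holds whole-number UMI counts per gene and cell, with no normalization. Reads were aligned with STAR 2.6.0a and the genome build was GRCz11, per the submitters' processing notes. The counting tool and the annotation release are not given in the sources used here. The table has 12409 rows and 184 cell columns, each matched to a sample by its barcode. Of the rows, 12354 are Ensembl genes, 54 are ERCC spike-in transcripts and 1 is the GFP reporter. Spike-in rows, 5.15% of all UMIs, stayed out of library sizes and comparisons. A symbol table named 11707 of the 12354 gene identifiers; the other 647 held 9.31% of UMIs. Many of its symbols are written in the human style without the zebrafish a or b suffix, and where several identifiers share a symbol the identifier is given. No genome was used here, so no coordinates are given.

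Genotype was taken from the labels, and the plate and column were read from the well code in the sample titles. Each sample is 1 cell and no animal or pool is named, so each genotype was treated as 1 sample. There is therefore no test, no standard error across animals and no count of significant genes. Doublets were not called, since cells were sorted singly into wells; the deepest cell, a wild-type cell with 33325 UMIs, holds 6.18% of wild-type UMIs, and results were repeated without it. Cells below 1000 UMIs were left out. UMIs were then summed per genotype, and CPM, the summed UMIs of a gene scaled by the summed UMIs of all genes, were computed here. Intervals of a CPM are exact Poisson, intervals of a ratio are exact conditional (Clopper-Pearson) and intervals of a share are exact binomial (Clopper-Pearson), all at 95%. They cover counting error only, neither variation between cells nor between animals. Medians of lists carry a binomial interval over members, or the range where members are fewer than 6.

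Before the data were examined, 22 gene lists, the cell type markers, the rule for named genes and most alternatives were fixed. A ribosomal protein list was taken by symbol. The symbols of the lists were matched regardless of case, and otherwise without a final a or b, to every gene with that symbol; this matching rule was chosen after the table was seen. A member was measured with at least 10 UMIs over both genotypes, and its log2 ratio used a prior of 1 UMI in each genotype. A list's median was placed among 10000 random lists of the same size, drawn from genes of neighbouring total UMIs, as a description of these libraries. Genes were named if they were emx2, or if the genotype with the higher CPM had at least 50 UMIs and a UMI in at least 10% of cells, with a ratio of at least 2, on the same side in each plate and still 2 or more without the highest cell of that genotype and in hair-cell-like cells. At most 12 genes a side were taken, ranked by the interval bound nearest to 1; with fewer than 5 on a side the limit was 1.5. From each list, up to 3 members with the most UMIs and up to 3 with the largest ratio, among those with at least 20 UMIs, were also open to naming.

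Clusters came from Leiden clustering with scanpy 1.11.5 and leidenalg 0.10.2 on log-normalised counts of 2000 variable genes, with 20 components, 10 neighbours, a resolution of 0.6 and seed 1. A cluster was hair-cell-like if at least 3 hair cell markers had a UMI in at least 50% of its cells and no other class had more markers among its 10 leading genes. To compare detection, each cell was thinned to 2000 UMIs. Alternatives were a minimum of 0 or 3000 UMIs per cell, the mean of per-cell CPM, edgeR 4.0.16 TMM factors and DESeq2 1.42.0 size factors on the 2 summed libraries, library sizes without mitochondrial and ribosomal protein genes, each plate alone, the highest cell left out, and other thinning depths, resolutions, member minimums and priors. Further alternatives, added after the data were seen, left out the 5 cells with over 20% spike-in UMIs, left out the deepest wild-type cell, left out cells in which pvalb8 made up under 20% of UMIs, kept the hair-cell-like clusters at a resolution of 1.2, or thinned every cell to 2000 UMIs before summing. Of the 5 cells high in spike-in UMIs, a wild-type cell with 866 UMIs was already left out for depth. The code used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, R 4.3.3 and matplotlib 3.10.9.

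The ratio and naming steps were tested on simulated data, with Poisson counts for 12355 genes at the real depths and 200 genes changed. The rule named 2% of 50 genes changed 1.5-fold, 50% of 50 changed 2-fold, and 100% of 50 changed 3-fold and of 50 changed 4-fold, and 0% of 932 unchanged genes. The interval held the simulated ratio for 88% to 98% of changed genes. The simulation had no variation between cells or animals beyond depth, so it tests the arithmetic only.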

Results

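Single hair cells of the zebrafish lateral line, the skin organ that senses water flow, were profiled at 6 days post fertilization in wild-type larvae and in larvae labelled as Emx2 mutants. Emx2 is a homeobox transcription factor that sets hair-bundle orientation in neuromasts, the small sensory patches of this organ, and the series title ties it to Notch signalling. Cells carrying a green fluorescent reporter driven by myo6b, a hair cell gene, were sorted from dissociated trunks, and their transcripts were counted by unique molecular identifiers (UMIs) at the 3′ end. The data hold 184 cells, 92 labelled mutant and 92 wild type. The first digit of each well code was read as the plate, which gives plate 2 and plate 4, each with 46 cells of either genotype. Columns 1 to 6 held the mutant-labelled cells and columns 7 to 12 the wild-type cells, so genotype and side of the plate coincide.

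Depth followed the plate. On plate 2 the median was 7560.5 UMIs in mutant-labelled and 6261.5 in wild-type cells, and on plate 4 it was 3682.5 and 3399 UMIs. The range over the 184 cells was 712 to 33325 UMIs. The median number of genes per cell was 1335 in mutant-labelled and 1176.5 in wild-type cells. Of the cells, 2 wild-type cells of plate 4 had fewer than 1000 UMIs and were left out, which leaves 92 mutant-labelled cells with 545364 UMIs and 90 wild-type cells with 537512 UMIs. No label names an animal or a pool, so each genotype counts as 1 sample. No p-value can be given, the differences have no replicate check, and all intervals are 95% intervals that cover counting error only.

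**Figure D1:**
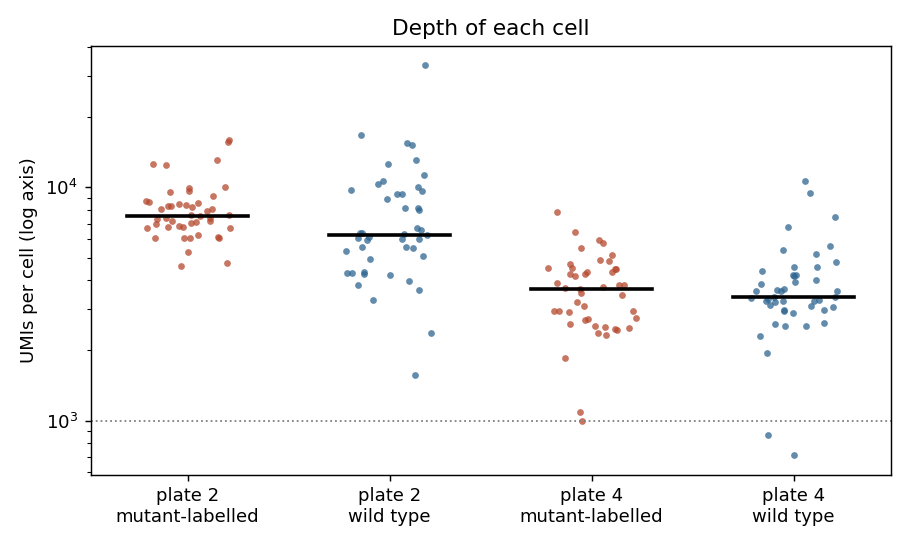
UMIs per cell on a log axis for each plate and genotype; each point is a cell, the black bar is the median and the dotted line marks 1000 UMIs. The plate 2 medians (7560.5 and 6261.5 UMIs) lie above those of plate 4 (3682.5 and 3399 UMIs).

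The sorted cells carried a hair cell transcriptome in both genotypes. The calcium buffer gene pvalb8 alone made up a median of 24.5% of a cell's UMIs in mutant-labelled cells and 22.9% in wild-type cells. At the main clustering resolution the cells formed 2 clusters, of 92 and 90 cells, which matched the plates except for 2 mutant-labelled cells. Both were hair-cell-like, with 8 and 6 hair cell markers present in at least 50% of their cells. The markers pvalb8, s100s and s100t had a UMI in all 92 mutant-labelled and 90 wild-type cells. Any grouping of these cells thus met the bar of 3 markers. As the clusters also followed the plates, the label does not part hair cells from other cells. The leukocyte list gathered 1 UMI in each genotype, the erythroid list 2 UMIs in mutant-labelled and 3 in wild-type cells, and the pigment and endothelium list 8 and 5 UMIs. Other lists were not near absent. The epidermis list gathered 937 and 1022 UMIs, the muscle list 858 and 1152 and the support cell list 1091 and 971. Much of each sum came from 1 gene seen in most cells. These genes were krt5 with 657 and 630 UMIs, atp2a1 with 402 and 699, and epcam with 445 and 451. The sums therefore do not measure the presence of those cell types. The neuron and glia list gathered 125 and 98 UMIs; its 4 measured members had a median log2 ratio of 0.34 (range -0.91 to 0.85), with 0.68 on plate 2 and -0.63 on plate 4.

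The first question was whether the level of emx2 itself differs between the labels. The transcript, listed as EMX2 (ENSDARG00000039701), was higher in mutant-labelled cells, at 193 CPM (UMIs of the gene scaled by all UMIs of the genotype; interval 157 to 233) from 105 UMIs against 83.7 CPM (61.1 to 112) from 45 UMIs in wild type. The ratio was 2.30 (1.61 to 3.34), with 2.18 on plate 2 and 2.48 on plate 4. Without thinning, the number of cells with any emx2 UMI was nearly equal, 39 of 92 mutant-labelled cells (42.4%, 32.1 to 53.1) and 36 of 90 wild-type cells (40%, 29.8 to 50.9). Cells with 3 or more emx2 UMIs numbered 13 of 92 (14.1%, 7.74 to 22.95) among mutant-labelled cells and 2 of 90 (2.22%, 0.270 to 7.80) among wild-type cells, with at most 10 and 3 UMIs in a cell. After each cell was thinned to 2000 UMIs, which left out 3 mutant-labelled and 4 wild-type cells, 22 of 89 (24.7%, 16.19 to 34.999) and 15 of 88 cells (17.05%, 9.87 to 26.6) kept an emx2 UMI, with overlapping intervals. Cells with 3 or more emx2 UMIs then numbered 5 of 89 (5.62%, 1.85 to 12.6) and 0 of 88 (0 to 4.11). The share with any emx2 UMI was higher in mutant-labelled cells at each thinning depth, with 17.4% against 8.89% at 1000 UMIs and 42% against 26.8% at 5000 UMIs, and the intervals overlap. The allele is not described in the sources used here, and a 3′ tag can lie outside the altered part, so the transcript level does not check the label. No cell type that should lack emx2 was measured, so the share of background UMIs is unknown.

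**Figure D2:**
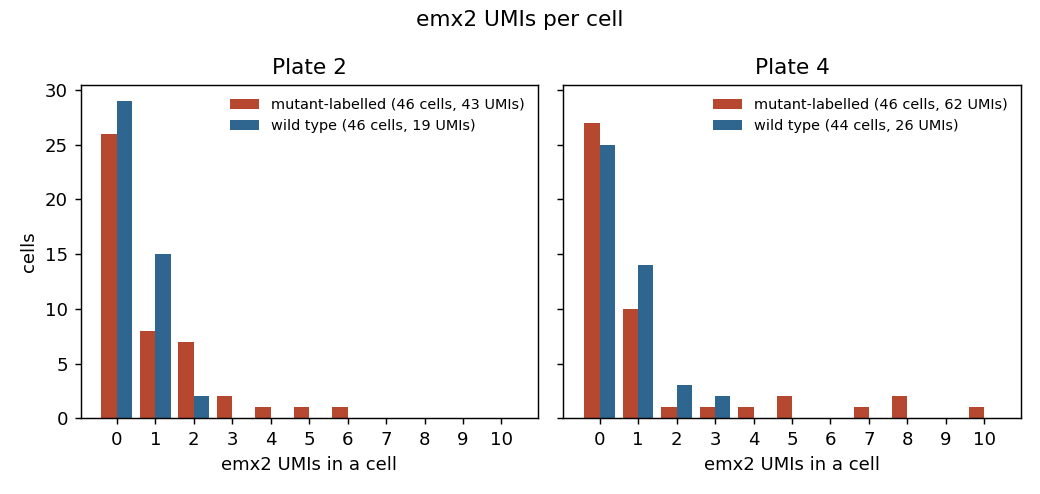
Number of cells (y axis) by emx2 UMIs in a cell (x axis), for plate 2 and plate 4 and both genotypes, without thinning. Cells with 3 or more UMIs number 13 in mutant-labelled and 2 in wild-type cells over both plates.

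Detection of emx2 was set beside that of Notch pathway genes and hair cell transcription factors in the same thinned cells. In wild type, emx2 had a UMI in 15 of 88 cells and the Notch ligand gene DLD in 28; both were seen in 3 cells, where independent detection gives 4.77. For the Notch target her4.5 both were seen in 3 cells against 1.36 expected, for ATOH1, the transcription factor that starts hair cell fate, in 4 against 3.24, and for gfi1aa in 9 against 8.18. In mutant-labelled cells the counts were 7 against 7.17 for DLD, 3 against 3.21 for her4.5, 3 against 2.97 for ATOH1 and 10 against 10.4 for gfi1aa. Over the genes examined, the widest gaps were 3 against 5.80 for EYA1 in wild type and 6 against 3.21 for POU4F3 in mutant-labelled cells. These counts are too few to show a departure from independence, which was not tested.

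The Notch pathway list stood above expression-matched lists. Of its 15 measured members, 12 were higher and 3 lower in mutant-labelled cells, with 7 higher and 1 lower in both plates. The 7 include NRARP (ENSDARG00000091419), with 12 mutant-labelled and 1 wild-type UMIs on plate 2 but 0 and 0 on plate 4. Its plate 4 log2 ratio of 0.056 came from the prior alone, so it has no plate 4 data. The median log2 ratio of the list was 0.39 (0.025 to 0.84), at percentile 97.9 of 10000 random lists. The median was 0.26 on plate 2, 0.90 on plate 4 and 0.19 in the clusters that stayed hair-cell-like at a finer resolution of 1.2. The Notch target her4.5 had 117 CPM against 35.3 CPM (ratio 3.32, 1.96 to 5.87), and LFNG, a glycosyltransferase that modifies Notch, had 58.7 against 9.30 CPM (ratio 6.31, 2.44 to 20.7). The LFNG value rests on plate 4, with 25 against 1 UMIs, since plate 2 had 7 against 4 (ratio 1.68, 0.428 to 7.84). Of the measured ligand genes, DLD had a ratio of 1.02 (0.788 to 1.31), jag2b 1.03 (0.718 to 1.49), dll4 1.299 (0.721 to 2.37), with 1.76 on plate 2 and 0.728 on plate 4, and dlb 1.38 (0.377 to 5.51) from 7 and 5 UMIs; all these intervals include 1. A close copy of her4.5, her4.1, had 9 mutant-labelled against 18 wild-type UMIs (ratio 0.493, 0.195 to 1.16); whether her4 copies share UMIs was not checked here, so their single values are uncertain.

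Support cell genes, which mark the cells around hair cells, went both ways. Of 13 measured members 7 were higher and 6 lower, with a median log2 ratio of 0.30 (-0.30 to 0.96) at percentile 97.3; with each cell weighted alike the median was -0.094. FNDC7 had 95.3 CPM against 27.9 CPM (ratio 3.42, 1.89 to 6.53), from 35 against 14 UMIs on plate 2 (ratio 2.40) and 17 against 1 on plate 4 (ratio 17.7). The glutamate transporter gene SLC1A3 had a ratio of 1.97 (1.304 to 3.03). Without cells in which pvalb8 made up under 20% of UMIs, 14 mutant-labelled and 26 wild-type cells, the list median was 0.0044 and the SLC1A3 ratio was 0.783. The epithelial genes epcam and cldnb had ratios of 0.972 (0.851 to 1.11) and 0.813 (0.628 to 1.05). For cldnb the plates went apart, with 0.541 (0.367 to 0.789) on plate 2 and 1.24 (0.859 to 1.80) on plate 4. The planar polarity list, which holds emx2 itself, had 8 of 11 members higher and a median of 0.37 (-0.71 to 1.08) at percentile 94.7, with 0.080 on plate 2 and 0.32 on plate 4. In it gnai1, a G protein subunit gene, had a ratio of 1.01 (0.739 to 1.38), and PRICKLE2, a core planar polarity gene, 2.199 (1.11 to 4.61). The plate 4 ratio of PRICKLE2 was 0.624 (0.0968 to 3.21), from only 3 mutant-labelled and 5 wild-type UMIs.

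Lists of hair cell identity and function had medians with intervals that include 0. The median log2 ratio was -0.12 (-0.56 to 0.17) over 12 hair cell transcription factors, 0.040 (-0.12 to 0.45) over 33 mechanotransduction and hair bundle genes, 0.14 (-0.012 to 0.41) over 22 ribbon synapse and calcium genes, 15 of them higher, 0.031 (-0.094 to 0.23) over 30 cilium genes and -0.16 (-0.95 to 0.68) over 8 young hair cell and progenitor genes. The ribbon synapse and calcium list lay at percentile 95.9 of random lists, with medians of 0.036 on plate 2 and 0.0034 on plate 4. Among the transcription factors, EYA1 and gfi1aa had ratios of 1.07 (0.861 to 1.32) and 0.887 (0.735 to 1.07), while six2b was lower in mutant-labelled cells at 0.542 (0.343 to 0.843), with 0.670 on plate 2 and 0.385 on plate 4. The ratio for ATOH1 was 0.674 (0.437 to 1.03). In the bundle list, MYO6 (ENSDARG00000042141), an unconventional myosin, was higher with a ratio of 1.34 (1.12 to 1.61) and grxcr1b lower with 0.535 (0.394 to 0.721), each on the same side in both plates. For calcium-binding proteins, pvalb8 had a ratio of 1.101 (1.09 to 1.11), s100s 1.195 (1.12 to 1.27) and s100t 0.991 (0.973 to 1.01). The reporter row, GFP, was lower in mutant-labelled cells, at 528 CPM against 820 CPM (ratio 0.644, 0.553 to 0.748); the protein made from this reporter set the sort gate, and without the cells low in pvalb8 the ratio was 0.886.

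**Figure D3:**
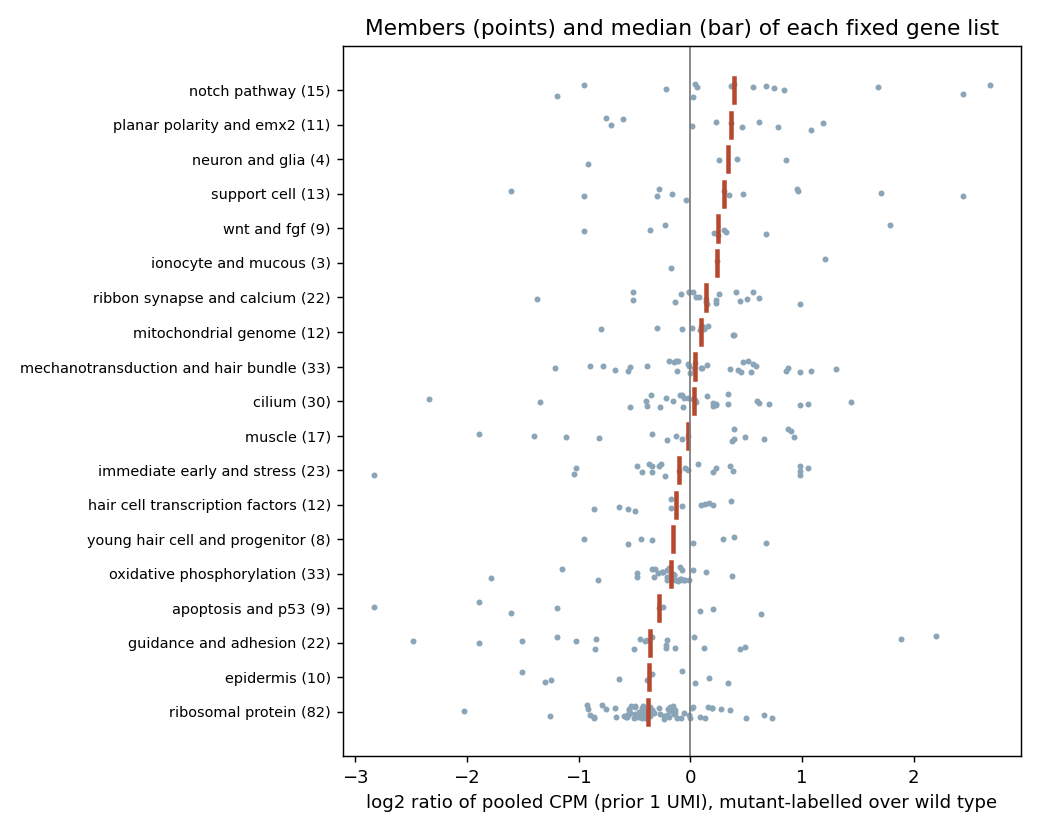
Log2 ratio of pooled CPM, mutant-labelled over wild type (x axis), for each fixed gene list with at least 3 measured members; points are members, the red bar is the median and the number of members is in parentheses. The Notch pathway median lies at 0.39 and the ribosomal protein median at -0.38.

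Pooled ribosomal protein transcripts were lower in mutant-labelled cells, and this moved with a set of cells low in pvalb8. Of 82 measured ribosomal protein genes 70 were lower and 12 higher, and 56 were lower in both plates; the median log2 ratio was -0.38 (-0.43 to -0.28), and none of the 10000 random lists had a lower median. The gene rpl32 had 1551 CPM against 2067 CPM (ratio 0.751, 0.685 to 0.821), RPS2 a ratio of 0.743 (0.673 to 0.821) and RPL29 a ratio of 0.527 (0.420 to 0.660). Cells with over 5% ribosomal protein UMIs numbered 4 of 92 mutant-labelled and 17 of 90 wild-type cells, and pvalb8 took a median of 15.9% and 12.8% of their UMIs, against 24.7% and 23.4% in the other cells of each genotype. Without the cells in which pvalb8 made up under 20% of UMIs, the list median was -0.039. The share of ribosomal protein UMIs per cell differed less at its median, 3.15% in mutant-labelled and 3.48% in wild-type cells on plate 2 and 2.86% in either genotype on plate 4; the upper quartile on plate 4 was 3.26% and 3.84%, and the highest cell had 6.05% and 9.57% over both plates. Of 33 nuclear oxidative phosphorylation genes 30 were lower, with a median of -0.17 (-0.24 to -0.10), at percentile 12.3 of random lists, whose middle value was -0.10; with TMM factors the median was -0.097. In that list cox6b1 had 40.3 against 143 CPM (ratio 0.282, 0.167 to 0.457) and UQCRC2 a ratio of 0.447 (0.318 to 0.622), while the abundant COX7C had 0.937 (0.869 to 1.01). Of the 12 mitochondrial genome genes 9 were higher, with a median of 0.098 (-0.075 to 0.15) and a summed ratio of 1.07 (1.05 to 1.09). The median over all 6288 genes with at least 10 UMIs was -0.051.

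Transcripts of the heat shock genes hsp70.1 and hsp70l were lower in mutant-labelled cells. hsp70.1 had 667 CPM (601 to 740) against 1360 CPM (1263 to 1462), with a ratio of 0.491 (0.432 to 0.557), and hsp70l, a near-identical gene that can share its UMIs, had a ratio of 0.486 (0.422 to 0.558). The ratios of hsp70.1 were 0.508 on plate 2 and 0.478 on plate 4. The other stress and immediate-early genes went both ways. JUN had a ratio of 0.854 (0.778 to 0.937) and egr1 2.22 (0.917 to 5.89). The egr1 ratio was 2.72 on plate 2, from 17 and 6 UMIs, and 0.520 on plate 4, from 1 and 2 UMIs. The median over the 23 members of the list was -0.10 (-0.34 to 0.23). The apoptosis and p53 list had a median of -0.28 (-1.90 to 0.20) over 9 members.

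The fixed rule for differences of at least 2-fold named 9 genes higher in mutant-labelled cells and 11 lower. Besides her4.5, FNDC7 and EMX2, the higher genes were mtus1a (ratio 3.05, 1.86 to 5.18), GAPDH (3.00, 1.81 to 5.18), a glycolytic enzyme gene, cald1a (2.36, 1.67 to 3.38), which encodes an actin-binding protein, tmsb1 (2.75, 1.60 to 4.92), a thymosin gene of actin binding, SNX12 (2.59, 1.59 to 4.33) and si:ch211-262i1.2 (2.24, 1.33 to 3.88). Besides cox6b1 and hsp70.1, the lower genes were ELAVL1 (0.291, 0.174 to 0.468), which encodes an RNA-binding protein, si:dkey-237g15.5 (0.286, 0.159 to 0.490), zgc:154006 (0.343, 0.233 to 0.495), TRAPPC6B (0.322, 0.175 to 0.566), RPS25 (0.413, 0.284 to 0.593; 0.650 without the cells low in pvalb8), ATP6V0C (ENSDARG00000036577; 0.347, 0.194 to 0.594), SPMIP7 (0.404, 0.263 to 0.609), NUDC (0.415, 0.266 to 0.635) and SEC11A (0.435, 0.289 to 0.645). The actin-related cald1a had a UMI in 50 mutant-labelled and 23 wild-type cells, and its ratio was 2.30 on plate 2 and 2.49 on plate 4. Counts behind these genes are low, such as 53 and 19 UMIs for tmsb1 or 17 and 52 UMIs for TRAPPC6B.

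**Figure D4:**
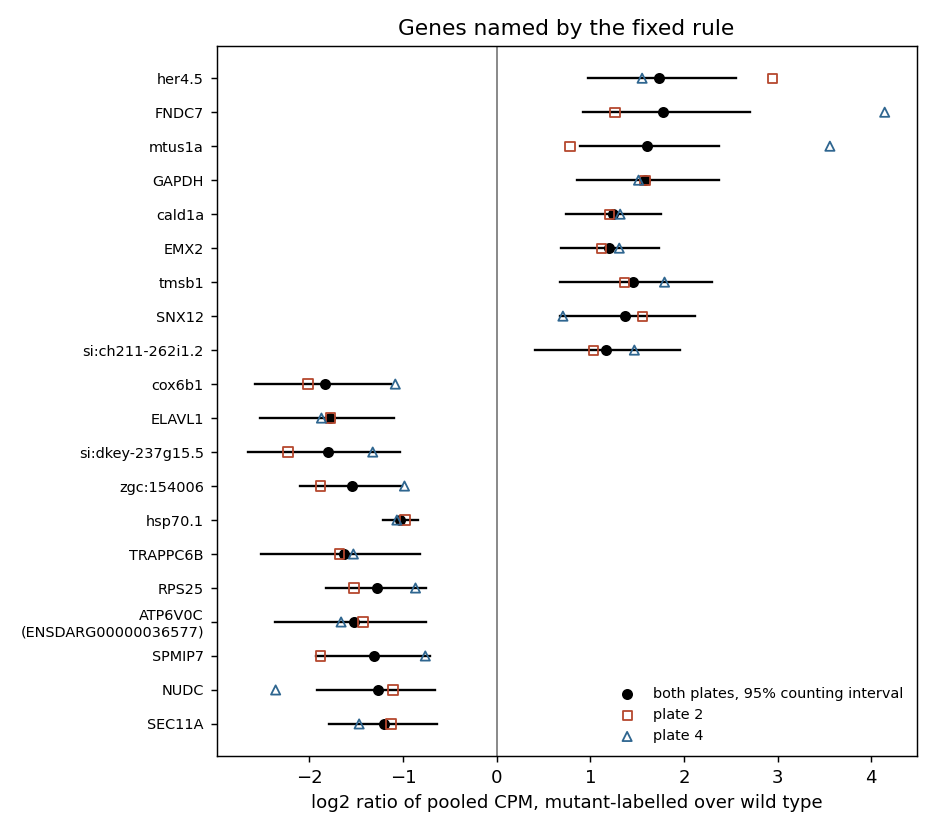
Log2 ratio of pooled CPM, mutant-labelled over wild type (x axis), for the 20 genes named by the rule; black points and bars give both plates with the 95% counting interval, open squares plate 2 and open triangles plate 4. Every gene lies on the same side of 0 in both plates, which the rule required.

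Lists of other tissues had medians whose intervals include 0. The epidermis list had a median log2 ratio of -0.37 (-1.30 to 0.17) over 10 members, -0.58 on plate 2 and -0.17 on plate 4. In it krt5 had 1205 CPM against 1172 CPM and krt91 a ratio of 0.399 (0.256 to 0.609). The plate 4 ratio of krt91 was 1.04, from only 2 and 2 UMIs. The muscle list had a median of -0.021 (-0.34 to 0.49) over 17 members, -0.12 on plate 2 and 0.19 on plate 4, in which atp2a1, a calcium pump gene of the sarcoplasmic reticulum, stood at 737 against 1300 CPM (ratio 0.567, 0.500 to 0.642). The ionocyte and mucous list had 3 measured members and a median of 0.24. The guidance and adhesion list had a median of -0.36 (-0.85 to 0.037) over 22 members, at percentile 7.15. By plate, however, its medians were -0.057 on plate 2 and -0.041 on plate 4. The neurotrophin gene BDNF had a ratio of 1.03 (0.887 to 1.19). Its plates went apart, with 1.16 (0.978 to 1.38) on plate 2 and 0.740 (0.557 to 0.979) on plate 4. The Wnt and Fgf list had a median of 0.25 (-0.36 to 0.68) over 9 members, 0.25 on plate 2 and 0.056 on plate 4. Only 2 cell cycle genes had 10 UMIs or more, with 24 mutant-labelled and 22 wild-type UMIs over the list. They went apart, PCNA with 14 mutant-labelled and 1 wild-type UMIs (ratio 13.8, 2.099 to 583), 12 and 1 of them on plate 4, and RRM1 with 6 and 8 UMIs; both were named after their values were seen.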

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

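The alternatives on cells with high spike-in shares, the deepest wild-type cell, cells low in pvalb8, the clusters at a resolution of 1.2 and thinning before summing were chosen after the data were seen. The emx2 ratio lay between 2.13 and 2.68 in every setting, and was 2.18 on plate 2 and 2.48 on plate 4. Of the 20 named genes, 16 kept the 2-fold limit on plate 4 alone and with cells thinned to 2000 UMIs, 17 without the cells low in pvalb8, 18 on plate 2 alone and with per-cell means, 19 with TMM factors and in the clusters at a resolution of 1.2, and 20 in the remaining settings. The rule already demanded this limit without the highest cell and in the main hair-cell-like clusters, so those settings add no check. It also chose genes on the pooled ratio and on the same side in each plate. The counts for each plate alone are therefore not independent checks. The hair-cell-like clusters at the main resolution hold every cell, so restriction to them moved nothing. Where a value moved or turned, the cause was not tested.

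On plate 4 alone the Notch pathway median was 0.90 and the oxidative phosphorylation median -0.26; with TMM factors the latter was -0.097 and the mitochondrial genome median 0.17. Thinning to 2000 UMIs gave -0.26 for oxidative phosphorylation and -0.044 for the ribbon synapse and calcium list. With no member minimum the ionocyte and mucous median was -0.60. The share of mutant-labelled cells with an emx2 UMI was 17.4% at 1000 UMIs, 42% at 5000 UMIs and 42.4% unthinned; in wild type it was 8.89% at 1000 UMIs, 26.8% at 5000 UMIs and 40% unthinned. The hair-cell-like share was 91.3% and 94.4% at a resolution of 1.2, and 93.2% of mutant-labelled cells with a minimum of 3000 UMIs. Median depth was 7560.5 and 6261.5 UMIs on plate 2 and 3682.5 and 3399 UMIs on plate 4. Some ratios of genes open to naming turned on plate 4 alone. Where the pooled interval excludes 1, these were 1.56 for IFT88, 1.04 for krt91, 0.624 for PRICKLE2, 0.797 for MT-ND2 and 1.01 for ATP5F1B. On plate 4 IFT88 had only 3 mutant-labelled and 2 wild-type UMIs, krt91 2 and 2, and PRICKLE2 3 and 5. Where the pooled interval includes 1, further ratios turned, such as 1.24 for cldnb and 0.520 for egr1. With thinned cells ATP1B1 (ENSDARG00000076833) turned to 0.879. Without the cells low in pvalb8 the ribosomal protein median was -0.039 and the SLC1A3 ratio turned to 0.783. Of 19 list medians, 4 changed sign on plate 4 alone, 4 with thinned cells, 4 with no member minimum, 3 with per-cell means and 2 without the cells low in pvalb8, all in lists whose interval includes 0. The support cell median was -0.094 with per-cell means. No paired analysis was possible because each genotype is 1 sample and the replicate numbers of the cells follow accession order; the plates hold both genotypes, and ratios within each plate stand beside the pooled ones. Plate 4 cells are shallow, so genes with few UMIs there give no firm ratio.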

Other observations

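Clustering at a finer resolution of 1.2 gave 8 clusters. Of these, 7 were hair-cell-like and 1, with 13 cells of plate 4, stayed unnamed; it held 8 mutant-labelled and 5 wild-type cells and was led by her4.5 and her4.2. Genes of the Notch list lead it, so its size is not compared between genotypes.

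Tests weighed here that were chosen only after the result was seen are the removal of the highest emx2 cell, the emx2 ratio on plate 4, the removal of the 9 highest heat shock cells, the median of the remaining stress genes, the count of shared plate columns, the choice of genes on 1 plate for the other and the removal of cells low in pvalb8. Thinning every cell before summing and the clusters at a resolution of 1.2 were also chosen after the data were seen, though the bound for the clusters was set before their ratios were computed. No animal is named, so a difference between the larvae or clutches behind the labels stays open for every pattern and was not tested.

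The emx2 transcript was 2.30-fold higher in mutant-labelled cells, with 13 such cells at 3 or more UMIs, or 5 after thinning to 2000 UMIs. Without the highest cell of each genotype the ratio was 2.23 (1.53 to 3.28). This argues against a single cell as its source, but not against a small set of cells. On plate 4, where median depths were closer, the ratio was 2.48 (1.54 to 4.08), which argues against uneven depth as the whole cause. With every cell thinned to 2000 UMIs it was 2.47 (1.40 to 4.54). Without the cells low in pvalb8 it was 2.68 (1.72 to 4.31), and in the hair-cell-like clusters at a resolution of 1.2 it was 2.13 (1.47 to 3.14); the latter interval reaches below the bound of 1.5 set for it, so cell makeup stays open in part. Whether the genotype itself sets the level was not tested.

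Heat shock transcripts, summed over the hsp70 and dnajb1 genes, were lower in mutant-labelled cells, with a ratio of 0.494 (0.450 to 0.541), 0.515 on plate 2 and 0.475 on plate 4. Of the 690 mutant-labelled UMIs, hsp70.1 held 364 and hsp70l 307. Of the 1378 wild-type UMIs they held 731 and 623. The sum thus follows these 2 near-identical genes and says little about dnajb1. Without the 9 cells of each genotype with the most heat shock UMIs the ratio was 0.481 (0.432 to 0.537), which argues against a few wells with damaged cells. The other 20 measured members of the list had a median log2 ratio of -0.034 (-0.28 to 0.35), which argues against a general immediate-early response of like size. The number of plate columns that hold both genotypes was 0, so heat or waiting time on one side of the plate and genotype cannot be told apart.

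Of the Notch pathway and support cell genes with at least 20 UMIs, 7 had a ratio of 1.5 or more: her4.4, her4.5, HEY1, LFNG, FNDC7, SLC1A3 and HMX3, chosen after their values were seen. Summed, their ratio was 2.52 (2.04 to 3.14), with 1.95 on plate 2 and 3.38 on plate 4. Since these genes were picked for their ratio, genes were also chosen on 1 plate and read on the other without its highest cell of each genotype. The minimum of 20 UMIs was counted over both plates, so the choice was not fully independent of the plate read. Among genes chosen on plate 2, HEY1 had 2 mutant-labelled and 1 wild-type UMIs there, and LFNG 7 and 4. Summed over the chosen genes, the ratio was 1.99 (1.35 to 2.96) on plate 4 and 1.36 (1.06 to 1.74) on plate 2. With the highest cells kept it was 2.58 (1.85 to 3.63) on plate 4 and 1.38 (1.11 to 1.73) on plate 2. Their removal thus moved the plate 2 value little. On plate 4 it left 80 of 129 mutant-labelled and 42 of 52 wild-type UMIs, so a part for single cells stays open. For the 7 genes the ratio was 1.89 (1.47 to 2.42) in the hair-cell-like clusters at a resolution of 1.2. It was 1.51 (1.105 to 2.08) without the cells low in pvalb8. The 13 cells outside the hair-cell-like clusters held 116 of the 307 mutant-labelled UMIs and 19 of the 120 wild-type UMIs. Within these 13 cells the ratio was 4.97 (3.04 to 8.55), and cells low in pvalb8 numbered 14 mutant-labelled and 26 wild-type. Without the cells low in pvalb8, 125 of the 307 mutant-labelled and 62 of the 120 wild-type UMIs remained. The genes were picked for their ratio, so these values cannot decide whether more mutant-labelled cells were not mature hair cells. Cell makeup and a difference within hair cells cannot be told apart, since the clusters were themselves built from such genes.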
